A study of Mus musculus with 2 samples.

How the data were processed

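Gene expression was measured on Affymetrix arrays in limb buds of wild-type CD1 mouse embryos at embryonic day 10.5. CD1 is an outbred stock. The buds were divided into anterior and posterior tissue, and the labels name 8 litters as the source of the embryos. Each tissue was pooled and hybridised to 1 array, so the series holds 2 arrays and neither group has a replicate. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on a column, amplified with a Nugen kit and labelled with biotin. The labels do not say whether forelimbs, hindlimbs or both were taken.

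The deposited values are RMA expression values on the log2 scale, 1 per transcript cluster (here called a probe set), from the core gene-level analysis of Affymetrix Expression Console, per the labels. The submitters' processing notes name the mouse build mm9; the software version is not given in the sources used here. RMA, as usually run, subtracts background, makes the distributions of the arrays equal by quantile normalization and summarises the probes of a probe set by median polish. It therefore removes an overall difference in brightness between the arrays, and it can compress ratios at low levels. Both columns of the table matched a sample by name, and there were 0 other columns. The median over all probe sets was 5.45 in the anterior array and 5.41 in the posterior array.

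The table held 23332 probe sets. The platform annotation gave exactly 1 gene symbol for 14996 of them, several symbols for 1019, and no entry for 7317, which stay unnamed here. Identifiers of 14941 single-symbol probe sets matched a mouse gene table of another assembly (GRCm38), which was used for names alone and changed 0 symbols. Probe sets of a symbol were averaged on the log2 scale, which gave 14860 genes, 135 of them with more than 1 probe set. Coordinates are not given, since no annotation of the build of the arrays was used here.

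The threshold was a difference of 1.3-fold, which the submitters named as their own selection. With 1 array per group no test of a single gene is possible, and no p-value is given. The following descriptions take the place of an error. The local spread of a gene is the robust standard deviation (1.4826 times the median absolute deviation) of the log2 ratios of the 500 genes nearest to it in mean level; it mixes array noise with true differences of those genes and is not a replicate error. A background set of 853 genes (olfactory, vomeronasal and bitter taste receptors and beta-defensins, none of them known from limb buds) set a detection floor at the 95th percentile of its values, 5.06 on the log2 scale. A gene was called detected where the higher of its values lay above that floor, which held for 9017 genes. Where the lower value of a detected gene lay under the floor, its fold is given as a lower bound against the floor, written "at least". Counts of genes past 1.3-fold use the measured values; a counted gene that was not detected, or whose bound is under 1.3-fold, is said to be so where it is named. For a gene list, the median log2 ratio was set against 10000 random lists of the same size, drawn member by member from the same of 20 bins of mean level, and its percentile among them describes these arrays only.

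Before the data were examined, 33 lists with 376 genes were fixed, and 319 of these genes were measured by a single-symbol probe set. No gene is on more than 1 list. A list is said to stand apart where its percentile lies below 2.5 or above 97.5; 5% of unrelated lists would do so by chance. The lists covered posterior patterning, anterior patterning, direct Hedgehog response, Hedgehog reception and transduction, HoxA, HoxB and the remaining HoxD genes, forelimb and hindlimb identity, the apical ectodermal ridge, ectoderm, the BMP, FGF, WNT, retinoic acid, Notch and Eph pathways, proximal limb, cartilage, muscle, endothelium, red blood cells, macrophages, neural cells, trunk and body wall, S phase, G2 and M phase, D cyclins, apoptosis, immediate early and stress genes, hypoxia and glycolysis, sex-linked genes and housekeeping genes. The rule for the genes named was fixed at the same time, and the text names those of them that show each group. They are the 10 detected genes with the largest difference in each direction (symbols that are only clone or predicted-gene numbers, and background genes, were passed over), up to 3 detected members of each list with the largest difference and the detected member furthest in the opposite direction, and a fixed set of Shh, Hand2, Gli1, Ptch1, Gli3, Alx4, Pax9, Irx3, Actb and Gapdh. Gapdh had no single-symbol probe set in the annotation used here. Other members are named where they complete a count of 1.3-fold genes or illustrate their list, and were chosen after their values were seen.

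The alternatives were a filter to detected genes, median-centred arrays, correction of the ratio for its trend with mean level (lowess, fraction 0.3), the brightest probe set per gene, an offset of 32 on the linear scale, probe sets in place of genes, thresholds of 1.5-fold and 2-fold, list means, and random lists not matched on level. The procedure was tested on simulated data with the levels and local spread of these arrays (14860 genes) and normally distributed noise. The trend was added for single genes but not for lists. Of 100 detected genes simulated with a 1.5-fold difference 89% passed 1.3-fold, of 100 with 2-fold 100% passed, and 2.82% of 8817 unchanged detected genes passed. The last share holds for normal noise and is no rate of false calls in these arrays. There 31.3% of the background set, most of it under the floor, passed. Of 100 simulated lists of 12 genes without a shift 95 fell in the central 95%, which their random draw gives by construction. Of 100 lists shifted by 0.3 on the log2 scale 100 stood apart. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.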

Results

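Anterior and posterior tissue of mouse limb buds at embryonic day 10.5 was profiled on 1 array each, to find genes whose expression differs along the anterior-posterior axis, the axis that runs from the thumb side to the little-finger side. Each array measured RNA pooled from several embryos, so the values are averages over animals with no replicate, and the number of arrays limits the precision of every value below. The arrays correlated with Pearson's r = 0.993 across 14860 genes, which are not independent replicates. Of these genes 8779 lay above the detection floor in the anterior array and 8775 in the posterior array.

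Shh, Hand2, Ptch1 and Gli1, known from posterior limb mesenchyme, were higher in posterior tissue, and Gli3 and Alx4, known from anterior mesenchyme, were higher in anterior tissue; these genes check the labels. Ptch1, the receptor of Sonic hedgehog and itself a target of the pathway, was 2.26-fold higher in posterior tissue (log2 difference 1.17, local spread 0.11). Gli1, a transcription factor induced by Hedgehog signalling, was 1.65-fold higher. Shh, the posterior signalling molecule, was under the floor in anterior tissue and at least 1.64-fold higher in posterior tissue (levels 4.80 and 5.77 on the log2 scale). Hand2, which acts upstream of Shh, was 1.56-fold higher in posterior tissue. On the anterior side, Gli3, the main Hedgehog-regulated repressor of the limb, was 1.47-fold higher and the homeobox gene Alx4 was 1.56-fold higher. Pax9 and Irx3, also known from anterior mesenchyme, did not pass 1.3-fold. Pax9 was under the floor in posterior tissue and at least 1.13-fold higher in anterior tissue, and Irx3 differed by 0.27 on the log2 scale toward anterior tissue. Actb, a reference gene, differed by 0.06 on the log2 scale with a local spread of 0.07.

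Across all genes, 560 were 1.3-fold or more higher in posterior tissue and 713 in anterior tissue by their measured values, without a test. Among the 9017 detected genes the numbers were 167 and 422, so that 71.6% of the differences were toward anterior tissue; 41 and 57 of them had a lower value under the floor and a bound under 1.3-fold. The ratio drifted with level: the median detected gene was 0.07 higher in anterior tissue on the log2 scale, and once the trend with level was removed 224 detected genes were higher in posterior and 281 in anterior tissue, or 55.6% anterior. Over all genes the same correction gave 573 and 613, and median-centred arrays gave 651 and 626. In the background set 267 of 853 genes (31.3%) passed 1.3-fold, 159 toward posterior and 108 toward anterior tissue. This set spread more than other genes near background, since 441 of 5042 genes not detected and outside the set (8.75%) passed. Among the 1486 genes of highest mean level, 2 passed toward posterior and 16 toward anterior tissue, or 1.21%.

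**Figure D1:**
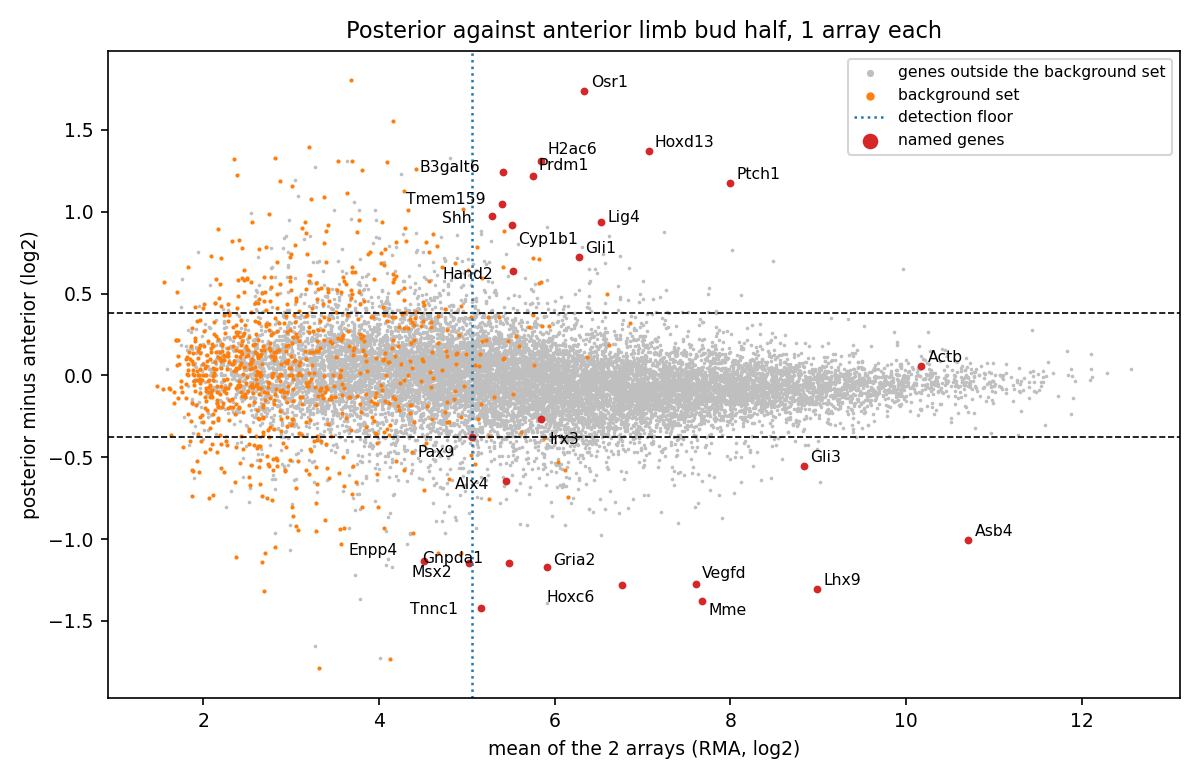
Log2 difference between posterior and anterior tissue (vertical axis) against the mean of both arrays (horizontal axis, RMA log2 values), 1 point per gene, with the 853 background genes in orange, dashed lines at 1.3-fold and a dotted line at the detection floor of 5.06. Osr1, Hoxd13 and Ptch1 stand above the cloud, Lhx9, Mme, Vegfd and Asb4 below it, and the cloud narrows with level.

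Among the detected genes that the naming rule did not pass over, the largest posterior difference was that of Osr1, a zinc-finger transcription factor. It was 3.34-fold higher (log2 difference 1.74, local spread 0.16). Hoxd13, the last gene of the HoxD cluster, followed at 2.58-fold with a local spread of 0.13. The histone gene H2ac6 was 2.48-fold higher. Core histone genes are near-identical copies, so its signal may be shared with others. Among 4 detected replication-dependent core histone genes 75% passed 1.3-fold. Whether few probes per gene add to such differences was not tested. Prdm1, a transcriptional repressor, was 2.32-fold higher, and Lig4, the DNA ligase of non-homologous end joining, 1.91-fold. B3galt6, an enzyme of glycosaminoglycan linker synthesis, Tmem159 and the cytochrome P450 gene Cyp1b1 were under the floor in anterior tissue and at least 1.96-fold, 1.82-fold and 1.89-fold higher in posterior tissue. Ptch1 and Shh complete the 10 posterior genes.

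On the anterior side, among the named genes above the floor in both tissues the largest difference was that of Mme. Mme, which encodes the peptidase neprilysin, was 2.60-fold higher in anterior tissue (log2 difference 1.38, local spread 0.13). The LIM homeobox gene Lhx9 was 2.47-fold higher, with levels of 9.64 in anterior and 8.34 in posterior tissue. Hoxc6 was 2.43-fold higher, and Vegfd, a growth factor of lymphatic endothelium, 2.42-fold. Asb4, a gene of anterior limb mesenchyme with a level of 11.21 in anterior tissue, was 2.01-fold higher, with a local spread of 0.07. Gria2, a glutamate receptor subunit, was 2.26-fold higher. Tnnc1, a troponin, Gnpda1, an enzyme of glucosamine metabolism, and Msx2, a homeobox gene induced by BMP signals, were under the floor in posterior tissue and at least 1.75-fold, 1.99-fold and 1.45-fold higher. For Enpp4 the bound was 1.01-fold. In each direction 1 clone or predicted gene, and 1 posterior and 2 anterior background genes, were as far apart as these and were passed over.

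Of the 13 posterior patterning genes measured, 7 were 1.3-fold or more higher in posterior tissue, none was higher in anterior tissue by that much, and all 13 had a posterior difference above 0. The 7 were Osr1, Hoxd13, Shh, Hand2, Tbx3, Tfap2b and Sall1. The median difference was 0.46 on the log2 scale, above all 10000 random lists. Tbx3 and Sall1, transcription factors of this list, differed by 0.58 and 0.46. Grem1, the BMP antagonist that links Shh to the ridge, differed by only 0.03, and Tbx2 by 0.08. Of the direct Hedgehog response genes, Ptch1 and Gli1 passed 1.3-fold, while Hhip was not detected; the median of the 3 was 0.72, at percentile 99.995 of the random lists.

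Of the 11 anterior patterning genes measured, 4 were 1.3-fold or more higher in anterior tissue, none in posterior tissue, and all 11 leaned toward anterior tissue. The 4 were Asb4, Alx4, Gli3 and Pax1, of which Pax1 fell under 1.3-fold after the correction for the trend with level. The median difference was 0.32 toward anterior tissue, below all 10000 random lists. The list of Hedgehog reception and transduction, which also holds genes of ligand processing and release (Hhat, Disp1 and the Scube genes), leaned the same way. In it 3 of 12 genes were past 1.3-fold toward anterior tissue by their measured values, with a median of 0.19 (percentile 1.16). Cdon and Boc, co-receptors that bind the ligand, were 1.83-fold and 1.36-fold higher, and the posterior value of Hhat, the acyltransferase of the ligand, lay under the floor, which leaves a bound of 1.23-fold, under the threshold. Of the members that act in transduction, Smo lay 0.20 toward anterior tissue. Sufu, Evc and Evc2, a ciliary protein, lay 0.02, 0.02 and 0.13 toward posterior tissue. After the correction for the trend with level this list no longer stood apart (percentile 2.7), and Boc fell just under 1.3-fold. Both patterning lists remained beyond all random lists.

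**Figure D2:**
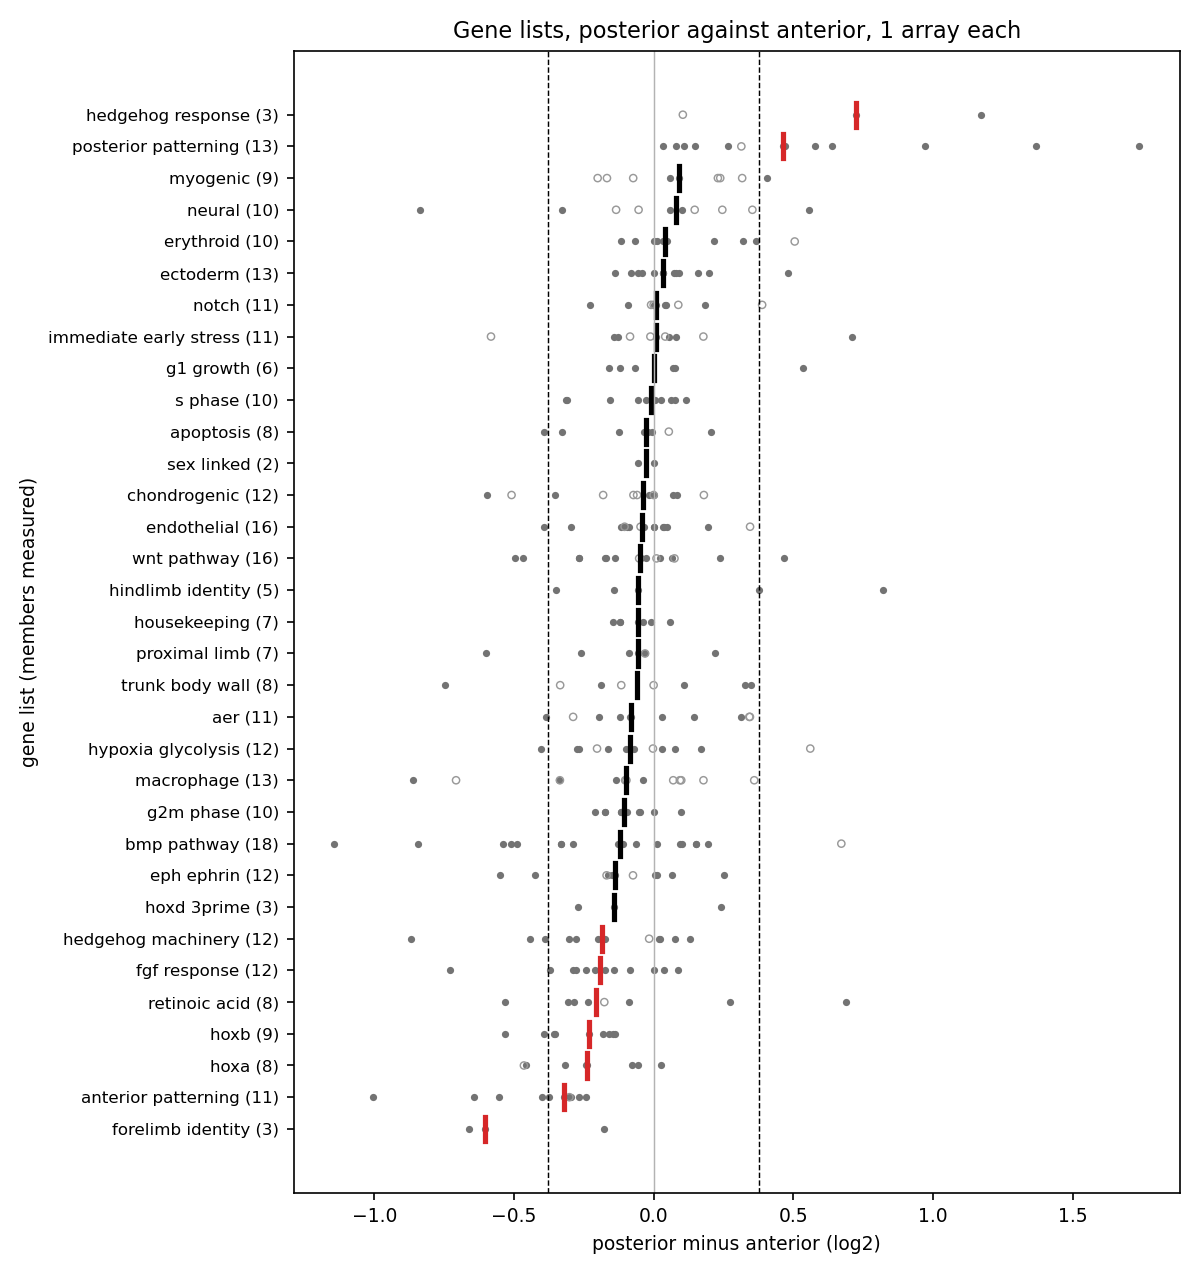
Log2 difference between posterior and anterior tissue (horizontal axis) for the measured members of each of the 33 gene lists (vertical axis, number measured in brackets). Filled points are detected genes, open points genes not detected, and the bar is the list median, red where it lies outside the central 95% of random lists; the Hedgehog response and posterior patterning lists lie highest and the forelimb identity and anterior patterning lists lowest. Dashed lines mark 1.3-fold.

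Hoxd13 was higher in posterior tissue, whereas most measured HoxA, HoxB and HoxC genes were lower there. The clusters were not tested against each other. Hoxa13 was not measured, and Hoxb13 and Hoxc13 were not detected. For the contrast with Hoxd13, cluster and position within the cluster therefore cannot be told apart. In HoxD, Hoxd13 was the only one of 6 measured genes past 1.3-fold, and Hoxd10 and Hoxd11 differed by 0.27 and 0.15 toward posterior tissue. Of the remaining HoxD genes Hoxd1 differed by 0.24 toward posterior and Hoxd9 by 0.27 toward anterior tissue (list of 3, percentile 19.4). Hoxd3, under the floor in posterior tissue, differed by 0.14 toward anterior tissue by its measured values. In HoxA, 7 of 8 measured genes and in HoxB 9 of 10 measured genes were lower in posterior tissue, with list medians of 0.24 and 0.23 toward anterior tissue (percentiles 1.0 and 1.04). The remaining HoxB gene, Hoxb13, was not on the list, was under the floor in both tissues and lay on the posterior side by its measured values. Hoxa6 was 1.37-fold and Hoxb2 1.44-fold higher in anterior tissue. Hoxa2 and Hoxb5 passed 1.3-fold by their measured values alone, since Hoxa2 was not detected and the bound of Hoxb5 was 1.16-fold. Hoxa10 differed by 0.02 toward posterior tissue, and Hoxa9 and Hoxa11 by 0.08 and 0.06 toward anterior tissue; the last 2 crossed 0 after the correction for the trend with level. In HoxC, which was set beside the others after the values were seen, all 8 measured genes were lower in posterior tissue by their measured values, and Hoxc12 and Hoxc13 among them were not detected. Past 1.3-fold by their measured values were 4, namely Hoxc4, Hoxc6, Hoxc8 and Hoxc5, the last with a bound of only 1.03-fold. Hoxc8 fell under 1.3-fold after the correction for the trend with level.

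**Figure D3:**
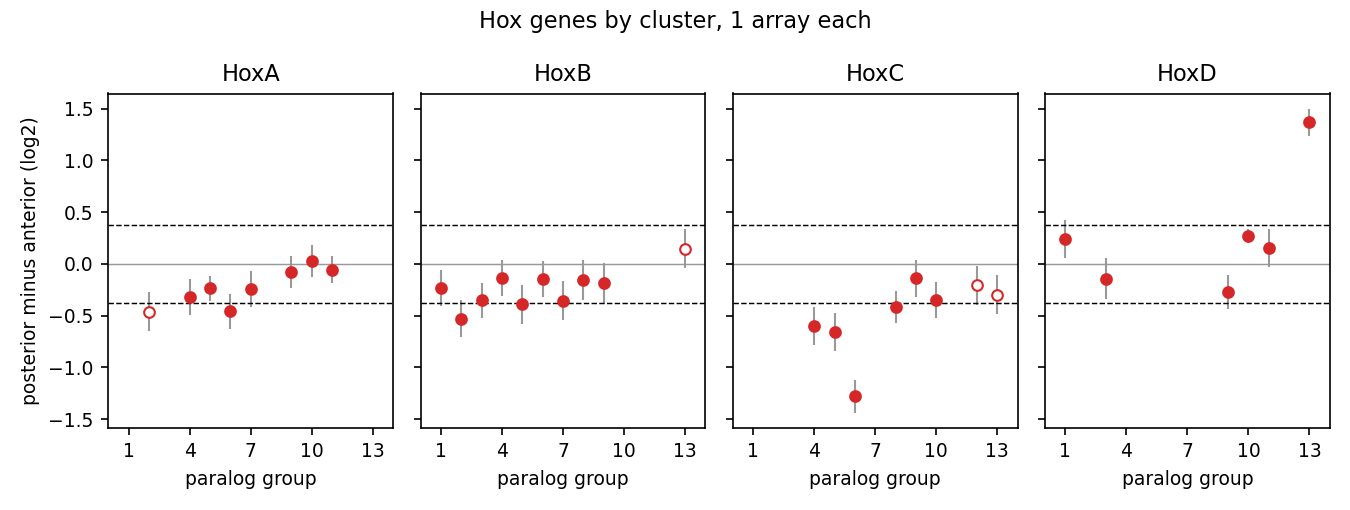
Log2 difference between posterior and anterior tissue (vertical axis) for the measured genes of each Hox cluster by paralog group (horizontal axis). Filled points are detected genes, open points genes not detected, bars the local spread of genes of the same level (not a replicate error), and dashed lines 1.3-fold; Hoxd13 at 1.37 and Hoxc6 at -1.28 are the extremes.

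Genes known to differ between forelimb and hindlimb were compared because the labels do not give the limb type. The forelimb-biased Tbx5 (levels 7.37 in anterior and 7.20 in posterior tissue) and the hindlimb-biased Tbx4 (6.86 and 7.24) lay above the floor in both tissues. Their levels do not give the share of each limb type in either pool. Of 3 forelimb-biased genes Hoxc4 was 1.52-fold and Hoxc5 at least 1.03-fold higher in anterior tissue, while Tbx5, the forelimb-specific T-box gene, differed by 0.18 (list median 0.60 toward anterior tissue, percentile 0.03). Of 5 hindlimb-biased genes Isl1 was 1.77-fold higher in posterior tissue, Tbx4 differed by 0.38, just under the threshold, Pitx1 differed by 0.05 toward anterior tissue and Hoxc10 by 0.35 toward anterior tissue (percentile 58.3). The mean of this list was 0.13 toward posterior tissue and stood apart (percentile 98.1), whereas its median was 0.05 toward anterior tissue. Tbx4 passed 1.3-fold toward posterior tissue after the correction for the trend with level.

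The BMP list did not stand apart from random lists by its median. Of its 18 genes, 5 were 1.3-fold or more higher in anterior tissue: Msx2, Msx1 at 1.79-fold, Id1 at 1.45-fold, Id2 and Bmp5. The response genes Id3 and Id4 differed by 0.29 and 0.33 the same way, under 1.3-fold. Smad6, Bambi and Smad7, also response genes, differed by 0.15 and 0.01 toward posterior and 0.06 toward anterior tissue. Smad7 crossed 0 after the correction for the trend with level. The only one past 1.3-fold toward posterior tissue by its measured values was the antagonist Nog, which was not detected. The list median, 0.12 toward anterior tissue, was at percentile 11.9, and its mean of 0.19 at percentile 0.73. The FGF list had a median of 0.19 toward anterior tissue (percentile 0.47). Of its 12 genes, Spry2, a feedback inhibitor, was 1.66-fold higher in anterior tissue and no other passed 1.3-fold, with the response gene Etv5 at 1.29-fold. The ligand Fgf10 differed by 0.09 toward posterior tissue, and the receptors Fgfr1 and Fgfr2 differed by 0.00 and 0.04. Retinoic acid genes split: Aldh1a2, the synthesising enzyme, was 1.61-fold higher in posterior tissue and the receptor Rarg 1.44-fold higher in anterior tissue. The other retinoic acid genes stayed under 1.3-fold, such as Crabp1, a binding protein, at 1.24-fold toward anterior tissue. The retinoic acid median was 0.21 toward anterior tissue (percentile 1.28), whereas its mean of 0.08 lay inside the random lists (percentile 40.8), and an offset of 32 on the linear scale also ended the call (percentile 3.0). Of 16 WNT genes, the secreted antagonists Wif1 and Frzb were 1.41-fold and 1.38-fold higher in anterior tissue, and Rspo3, a WNT enhancer, 1.38-fold higher in posterior tissue (percentile 64.9). Of 12 Eph receptors and ephrins, Efna5 and Efnb2 were 1.47-fold and 1.34-fold higher in anterior tissue and Epha3 differed by 0.25 toward posterior tissue (percentile 4.96). Efnb2 fell under 1.3-fold after the correction for the trend with level. Of 11 Notch genes only Hey2 passed 1.3-fold, by its measured values and without being detected; Notch2 differed by 0.23 toward anterior tissue and Lfng was at least 1.13-fold higher in posterior tissue (percentile 69.96).

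Among growth and differentiation genes, Cdk6, a cyclin-dependent kinase, was 1.45-fold higher in posterior tissue, the only one of 6 D cyclins and partners past 1.3-fold (percentile 89.8), with Mycn at 1.12-fold toward anterior tissue. None of 10 S phase genes (percentile 93.9) and none of 10 G2 and M phase genes (percentile 11.9) passed 1.3-fold; the largest differences were those of Ccne1 and Plk1, at 1.24-fold and 1.16-fold toward anterior tissue. Of 12 cartilage genes Sox5 was 1.51-fold higher in anterior tissue, Cnmd passed without being detected, and Sox9, the master regulator of cartilage, differed by 0.02 (percentile 41.2). Of 7 proximal limb genes Pbx3 was 1.52-fold higher in anterior tissue, Meis1 differed by 0.26 the same way, and Shox2 by 0.22 toward posterior tissue (percentile 61.1). Of 8 pro-apoptotic genes Pmaip1 was 1.31-fold higher in anterior tissue and Casp8 differed by 0.21 toward posterior tissue (percentile 68.8). Of 12 hypoxia and glycolysis genes Ankrd37 was 1.32-fold higher in anterior tissue and Adm, not detected, passed toward posterior tissue (percentile 26.1). Pmaip1 and Ankrd37 fell under 1.3-fold after the correction for the trend with level.

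Markers of other cell types and of the dissection were compared in the same way. Of 11 ridge genes Dlx5 was 1.31-fold higher in anterior tissue, and Fgf4 and Fgf8, ridge growth factors, differed by 0.31 toward posterior and 0.12 toward anterior tissue (percentile 26.1). After the correction for the trend with level Dlx5 fell under 1.3-fold, and Fgf4 just passed it toward posterior tissue. Of 13 ectoderm genes only Krt5, a keratin, passed, at 1.40-fold toward posterior tissue, and Epcam differed by 0.14 toward anterior tissue (percentile 93.6). Of 16 endothelial genes only Plvap passed 1.3-fold by its measured values, toward anterior tissue, with a bound of 1.03-fold that is under the threshold, and Cdh5 differed by 0.03 (percentile 53.6). The embryonic globin genes Hbb-y and Hba-x differed by 0.01 and 0.00, and of 10 red blood cell genes only Klf1, not detected, passed 1.3-fold, toward posterior tissue (percentile 93.5, and 98.3 after the correction for the trend). Of 13 macrophage genes Tyrobp was 1.82-fold higher in anterior tissue and C1qa passed the same way without being detected (percentile 6.29). Of 9 muscle progenitor genes Myod1 alone passed by its measured values, toward posterior tissue, with a bound of 1.03-fold that is under the threshold, and Pax3 differed by 0.06 (percentile 88.1, and 98.8 after the correction). Only 3 of these 9 genes were detected. Of 10 neural genes Dcx was 1.79-fold higher in anterior and Nefm 1.47-fold higher in posterior tissue (percentile 90.4). Of 8 trunk and body wall genes Foxc2 was at least 1.39-fold higher in anterior tissue, and Gata4 and Wt1 were 1.27-fold and 1.25-fold higher in posterior tissue (percentile 24.1). Of 11 immediate early and stress genes Hspa1a passed 1.3-fold by its measured values toward posterior tissue, with a bound of 1.24-fold, and Atf3, not detected, toward anterior tissue (percentile 68.3). The Y-linked genes Kdm5d and Eif2s3y differed by 0.06 and 0.00 (percentile 71.7), and none of 7 housekeeping genes passed 1.3-fold (percentile 51.6).

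In all, 9 of the 33 lists stood apart from random lists, 2 toward posterior tissue and 7 toward anterior tissue. The 5% by chance holds for unrelated genes, which these lists do not hold, so it is no error rate for this count. HoxA, HoxB and forelimb identity rest wholly or mainly on Hox genes. Hedgehog reception and transduction lost its call after the trend correction (percentile 2.7), and retinoic acid by its mean (percentile 40.8). Muscle and red blood cells stood apart toward posterior tissue after the trend correction (percentiles 98.8 and 98.3). Only 3 of the 9 muscle genes measured were detected, and without the correction these 3 alone lay inside the random lists (percentile 89.1). Lists of 3 genes (Hedgehog response, forelimb identity) rest on very few values.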

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

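All tests in this part except the comparison of intronless with intron-bearing genes were chosen after the result was seen, as was the interval set on that comparison. Probe sets without a gene name entered no gene or list comparison, only the count over all probe sets, yet they carried large differences. Of 4152 such probe sets above the detection floor, 1376 (33.1%) passed 1.3-fold, 593 toward posterior and 783 toward anterior tissue, and 250 differed by 2-fold or more. Of 8965 named genes above the floor and outside the background set, 565 (6.30%) passed and 19 differed by 2-fold or more.

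Of the 853 background genes, counted at all levels, 31.3% passed, and this is far above other genes. Only 52 of them lay above the floor, so this share and that of the unnamed probe sets cover unlike levels. The tables argue against low level as the whole cause, because in 1000 draws of other genes at the same levels 6.21% to 11.96% passed, and the background share was 2.62 times the highest draw. A candidate explanation is that genes without introns carry few probes on an array whose probes are spread over exons, so that 1 odd probe moves the summary. Intronless receptor genes passed 1.10 times as often as beta-defensins, which have introns, and a quotient under 1.2 had been set beforehand as counting against the explanation. That bound took no account of the number of defensins: 21 were measured, 6 of them past 1.3-fold, and the exact 95% interval of their share (11.3% to 52.2%) allows a quotient between 0.60 and 2.77, so the explanation stays open. The number of probes per probe set was not used here, and no biological explanation was tested.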

How the results depend on the processing

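The 99th-percentile floor and the combination of detected genes with the trend correction were chosen after seeing the data. Counts at 1.3-fold were made without a test and changed with the treatment of genes near background. The counts of 560 posterior and 713 anterior genes became 167 and 422 with detected genes only, 60 and 157 with an offset of 32 on the linear scale, 199 and 226 at 1.5-fold, 36 and 31 at 2-fold, and 1914 and 2314 with all probe sets in place of genes. Detected genes with the trend removed gave 224 and 281, and a floor at the 99th percentile of the background set gave 76 and 293. Median-centred arrays, the trend correction over all genes and the brightest probe set stayed within 1.5 times the first counts. The 267 background genes became 133 at 1.5-fold and 29 at 2-fold. Of 231 list values under alternatives, 199 moved by less than the standard deviation of the random medians, and no list that stood apart changed sign. Part of this share was fixed by the settings. Random lists not matched on level leave the list value as it is, and median-centring moves every ratio by the same small amount. Log2 values in this paragraph are posterior minus anterior. The trend correction moved posterior patterning to 0.56, Hedgehog transduction to -0.10, HoxA to -0.15, BMP to -0.048, FGF to -0.12, muscle to 0.18, red blood cells to 0.12, S phase to 0.060, G2 and M phase to -0.052, Eph genes to -0.078 and housekeeping genes to -0.00011. The linear offset, which shrinks ratios of low genes by construction, gave posterior patterning 0.36, Hedgehog response 0.51, anterior patterning -0.19, HoxB -0.14, forelimb identity -0.30, retinoic acid -0.14 (percentile 3.0, no longer apart) and Eph genes -0.081. Means in place of medians gave posterior patterning 0.55, anterior patterning -0.43, hindlimb identity 0.13 (percentile 98.1), the ridge 0.0022, BMP -0.19, retinoic acid -0.083, proximal limb -0.12, cartilage -0.12, red blood cells 0.13 (percentile 99.4) and S phase -0.058. Detected members only gave Hedgehog response 0.95, WNT -0.14, macrophages -0.24 and trunk 0.11. Muscle also stood apart under the linear offset (percentile 98.1) and macrophages by their mean (percentile 2.42). Only 3 of 9 muscle genes and 4 of 13 macrophage genes were detected. Random lists not matched on level changed no call. Of 620 values of the 124 named genes, 583 moved by less than the local spread, 37 moved further, all under the linear offset, and 0 changed sign among genes past 1.3-fold. Most of these values could hardly move. The named genes were all detected, so the filter left them unchanged, and the brightest probe set alters only genes with more than 1 probe set. The share of 583 is therefore no measure of robustness. Except where the setting itself shows it, the cause of a move was not tested. No paired analysis was possible because each tissue has 1 array. Genes with 2 probe sets allowed ratios to be compared within a gene. Of 95 detected ones, 20 had a probe set past 1.3-fold, in 12 of them both probe sets pointed the same way, and in 0 did both pass (r = 0.11 across genes). Whether these genes stand for those with 1 probe set was not tested.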

Other observations

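Of the tests in this part, the one of the Hox genes against the trend with level was chosen before its result was seen, and the others after. Of 3799 genes with a mean level of 7 or more, a limit set after the data were seen, 29 were at least 1.5-fold higher in anterior tissue and 6 in posterior tissue, or 14 and 9 after the trend with level was removed; the local spread there was 0.07 to 0.15. The anterior genes included the LIM homeobox gene Lhx2 at 1.72-fold beside Lhx9, the homeobox gene Prrx2 at 1.74-fold, Snai2, a repressor of epithelial genes, at 1.59-fold, the membrane proteoglycan gene Sdc2 at 1.66-fold, the collagen gene Col1a2 at 1.57-fold and Cdo1, an enzyme of cysteine breakdown, at 1.57-fold. After the correction Snai2, Col1a2 and Cdo1 fell under 1.5-fold, with differences of 0.58, 0.56 and 0.58 on the log2 scale toward anterior tissue. The posterior genes included Hoxd13, Ptch1, the matrix gene Frem1 at 1.84-fold, Itm2a, a membrane protein, at 1.70-fold and the transcription factor Ets2 at 1.62-fold.

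Detected genes past 1.3-fold were more often higher in anterior tissue (422 against 167), a quotient that shrank to 1.25 (281 against 224) once the trend with level was removed. That correction centres the ratio at every level and so draws the counts together in any case, which leaves a level-dependent offset between the arrays open as a candidate explanation and does not decide it. A real difference spread over many genes would look the same with 1 array per tissue, and it was not tested.

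Of 22 detected HoxA, HoxB and HoxC genes, a set put together after the values were seen, 21 were lower in posterior tissue, with a median of -0.28 (posterior minus anterior, log2). The tables argue against the trend with level as the whole cause: the median after its removal was -0.21, and the lists fixed before the data were examined stayed outside the central 95% of random lists (HoxA percentile 1.32, HoxB 1.30), although Hoxa9 and Hoxa11 crossed 0. Trunk tissue carried along with anterior buds could raise Hox genes, but 5 detected somite and body wall genes (Meox1, Uncx, Wt1, Gata4 and Foxc2, with levels up to 5.85; 3 listed genes were not detected) had a median of 0.11 and went both ways, which decides nothing; an earlier criterion, replaced after its outcome was seen, had counted the higher posterior values of Gata4 (1.27-fold) and Wt1 (1.25-fold) against it. Unequal shares of fore- and hindlimbs cannot be told apart from position within the bud: of the detected hindlimb genes that are not Hox genes, 0 lay below the median gene by more than the local spread, but Pitx1 differed by 0.05 toward anterior tissue while Isl1 and Tbx4 leaned toward posterior tissue, and the mean of the whole hindlimb list (0.13, percentile 98.1) stood apart toward posterior tissue where its median did not. A hypothesis that these clusters are themselves graded along the axis, opposite to Hoxd13, would need replicate pools with limb type recorded.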
